A study of Drosophila melanogaster with 4 samples.

How the data were processed

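RNA was taken from dissected larval trachea of Drosophila melanogaster after infection with Erwinia carotovora Ecc2141 and from uninfected controls. Per the labels' protocols, about 200 larvae in their second instar were kept for 30 min with 200 µl of a bacterial pellet of OD 200, or with buffer, and crushed banana, and were then reared at 29 °C on corn-meal medium. The tracheae are labelled as of the third instar, at an age of 10 days. RNA of 20 pairs of tracheae was extracted, reverse-transcribed, amplified as cDNA by the CapFinder method, transcribed to amino-allyl RNA and coupled to Cy3 or Cy5, per the labels' protocols. The dye of each channel was taken from its label field; the free-text labelling protocol gives the other dye on the arrays with infected RNA in Cy5. The direction found from the values, given below, does not depend on that text.

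The deposited values are log2 ratios per spot, 32448 spots on each of 4 arrays, with no missing value. Scanner files and intensities were not analysed here, so background, dye correction and dim spots could not be examined, and the software steps behind the values are not given in the sources used here. Scale, direction and centring were found from the values. The means and SDs over adjacent pairs of spots recurred in the authors' deposited table for 332 of its 349 genes with 8 spots (tolerance 0.006), for 38 when the arrays with infected RNA in Cy3 were turned, for 46 when all signs were turned, and for 50 after centring. The values were therefore read as log2 of infected over uninfected on all arrays, not centred. Array medians were -0.47 and 0.61 in replicate 1 (infected RNA in Cy5 and in Cy3) and -0.32 and 0.13 in replicate 2, with SDs of 1.35, 1.21, 1.20 and 1.76. The median over the means of all probes was 0.00125, so centring shifts the average ratio by far less than the smallest listed size. The spots carry no gene names in the files used, and none was assigned by value, beyond the probable match of GFP given below.

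A second file is a table the authors made with SAM and GeneTraffic, per the series' design text, whose versions and thresholds are not given in the sources used here. Per the file headers, it gives for each gene the authors' mean log2 ratio, the SD over valid spots, the number of valid spots, the coefficient of variation, a name and functional terms. Its absolute means start at 0.59, its spots run from 6 to 24, its coefficients of variation reach 0.99, and its median SD is 0.69. SDs from that table are over spots of pooled arrays and are not an error between biological replicates. Gene identifiers were matched to current symbols in a RefSeq gene table of the Release 6 assembly: 660 by locus tag, 22 by synonym and 1 by symbol, while 12 had no match and keep the name in the file. The same table gave genomic spans, introns included, for 683 of the 695 genes. The files name no genome build, and current gene models can differ from those behind the array, so spans were used only to compare sets of genes, by permutation of median log2 span (two-sided, 100000 resamples). Folds were computed as 2 to the power of the absolute mean.

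Adjacent spots were averaged as duplicates of a probe, giving 16224 probes. This layout was inferred from the higher correlation of such pairs. The arrays of a dye-swap pair come from the same RNA and were averaged, which leaves 2 biological replicates. The replicate means were tested against 0 with limma 3.58.1 (lmFit and eBayes, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The labels name biological replicates without saying how the larvae were kept apart. On simulated data with 200 of 16224 probes changed, averaged over 20 simulations, the procedure recovered 25.5%, 77.1%, 99% and 99.9% of probes with log2 changes of 2, 3, 4 and 5, and 6.80% of its calls were false.

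A set of 35 gene lists (pathways, complexes, and markers of tissues that dissection can leave attached) was fixed before the data were examined. The planned rotation and camera tests need gene names on the probes, and a count adjusted over the list alone needs a p per gene, so neither could be run. In their place, listed members above and below 0 were compared with all other genes of the authors' deposited table by two-sided Fisher's exact tests, adjusted over the 13 lists with at least 3 listed genes. These tests ask only for direction among genes the authors had selected; the array's full gene content was not used here. On simulated directions (200 simulations over 695 genes) the ribosomal protein list, with its 13 listed genes made wholly lower, was recovered in 100%. With all 13 made lower, that recovery was nearly fixed by the counts and says little of power. A false list appeared in 1%, with directions exchanged freely among genes. Genes that change together, as members of a complex may, were not simulated. Recovery of smaller lists was not simulated, and 4 or 3 genes, all higher, give an unadjusted Fisher's exact p of 0.125 or 0.250. Lists of those sizes could thus not pass by lying wholly higher. Functional terms with at least 8 listed genes were tested in the same way and adjusted over 67 terms. Of the list symbols, 2 had no match. Fisher's tests used scipy 1.17.1 and adjustment statsmodels 0.14.6, under Python 3.11.15 with pandas 2.3.3; figures were drawn with matplotlib 3.10.9.

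The rule for named genes was written for probes before the data were examined. It was applied to the authors' deposited table: the 12 highest and 12 lowest means, up to 4 members of each fixed list, and every listed antimicrobial peptide and recognition gene. Genes named outside it are said to be so. Alternatives covered the treatment of arrays and dyes, centring and scaling, other thresholds, a SAM statistic over all 16 sign flips, each array left out in turn, and stricter subsets of the authors' deposited table. Each of 22 per-array series (array summaries and called probes) was searched for a single stray array with Dixon's test for 4 values, and 0 were found. Of these series 19 were probes already selected by limma, and with 4 values only an extreme stray passes. The search therefore says little about the quality of the arrays.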

Results

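The response of the larval airway to a bacterial infection was measured in Drosophila melanogaster. The trachea, the branched epithelial tube system that carries air to the tissues, was dissected from larvae that had been fed Erwinia carotovora Ecc2141, a gram-negative bacterium, and from larvae fed buffer. The strain, YW DD1, carries a GFP reporter of the immune reaction, and infected larvae were taken once GFP was seen along the whole airway epithelium. Each of 4 two-colour arrays set infected against uninfected trachea. They form 2 biological replicates, each hybridised once with the infected RNA in Cy5 and once, as a technical repeat, with the infected RNA in Cy3. All ratios below are log2 of infected over uninfected, so that a value above 0 means a higher level in infected trachea. The number of arrays limits the precision of every value. The p-values of gene lists come from counts of genes in a table made by the authors and hold no spread between replicates.

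The first question was which genes differed between infected and uninfected airways. The authors' deposited table lists 695 genes as regulated, 359 of them higher and 336 lower in infected trachea, and gives for each the mean over its valid spots on the arrays. At its top, the authors' deposited table has GFP itself, at 4.73 (SD 2.27 over 8 spots), a 26.5-fold higher level. The infected larvae were chosen by their GFP signal, so this value reflects the choice as well as the response. Next in the authors' deposited table comes ple (CG10118), which encodes tyrosine hydroxylase, the first enzyme of dopamine synthesis, at 4.36 (SD 0.73, 6 spots) or 20.5-fold higher. It is followed in the authors' deposited table by Drsl4 (CG32282), a peptide of the antifungal drosomycin family, at 4.16 (SD 0.37, 8 spots) or 17.9-fold higher.

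Beyond these, the 12 highest entries of the authors' deposited table hold bwa, an alkaline ceramidase, at 3.40 (SD 2.38, 6 spots), Jon99Ciii, a serine protease of the gut, at 3.16 (SD 1.15, 8 spots), Listericin, an antibacterial peptide, at 2.99 (SD 0.78, 8 spots), and Def, which encodes Defensin, at 2.84 (SD 1.54, 8 spots). The same part of the authors' deposited table holds Ccp84Ag, a cuticle protein gene, at 2.78 (SD 1.08, 8 spots) and Ddc, the dopa decarboxylase that acts after tyrosine hydroxylase, at 2.73 (SD 1.62, 8 spots). The other entries among those 12 in the authors' deposited table, CG15096 at 3.31 (SD 0.63), CG11413 at 3.01 (SD 0.82) and CG4757 at 2.76 (SD 1.59), rest on 8 spots each.

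At the lower end, the authors' deposited table has Tim9a, a chaperone of protein import into mitochondria, at -2.76 (SD 0.53, 8 spots), a 6.77-fold lower level. REPTOR-BP, a transcription factor that acts downstream of the growth regulator TORC1, stood at -2.61 (SD 0.61, 8 spots) in the authors' deposited table. Aos1, a subunit of the enzyme that activates SUMO, stood at -2.52 (SD 1.55, 7 spots), and SmD1, a core protein of the spliceosomal ribonucleoproteins, at -2.47 (SD 0.89, 8 spots) in the authors' deposited table. Among the 12 lowest entries of the authors' deposited table were also the insulator-binding Ibf2 at -2.26 (SD 1.29), cold, a septate junction gene, at -2.19 (SD 0.80), and Ance-3 at -2.18 (SD 0.42), each over 6 spots. The remaining low entries of the authors' deposited table were CG11686 at -2.57 (SD 1.22), CG7519 at -2.53 (SD 1.09), CG17272 at -2.26 (SD 0.44), CG2021 at -2.19 (SD 0.54) and CG5757 at -2.18 (SD 0.52).

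The immune genes were taken as lists fixed before the data were examined, and each list was asked whether its listed members lay on one side more often than the other listed genes. Of 21 antimicrobial peptide genes, 4 are in the authors' deposited table and all 4 are higher: Drsl4, Def, Mtk at 1.83 (SD 1.43, 6 spots) and AttA at 1.16 (SD 1.00, 7 spots). Metchnikowin, the product of Mtk, acts mainly on fungi, and attacins act on gram-negative bacteria. Of 17 other immune-induced peptide genes, the authors' deposited table holds 3, all higher, with Listericin joined by BomS2, a Bomanin, at 2.07 (SD 0.50, 6 spots) and BaraA2 at 1.93 (SD 0.39, 6 spots). Among 17 genes of the peptidoglycan and glucan recognition list, the authors' deposited table again holds 3, all higher: PGRP-LA at 2.27 (SD 0.41, 6 spots), PGRP-SD at 1.73 (SD 1.34, 6 spots) and GNBP3 at 0.73 (SD 0.25, 6 spots). None of these small lists passed Fisher's exact test alone, with a two-sided adjusted p of 0.405 for the antimicrobial peptides and 0.541 for each of the others. With 4 or 3 listed genes, all higher, the unadjusted Fisher's exact p is already 0.125 or 0.250. Lists of these sizes could therefore not pass by lying wholly higher, and their misses are no evidence against a rise. A pooling of these lists, chosen after their values were seen, gave 10 genes higher and 0 lower (two-sided Fisher's exact p = 0.00192). Not every immune-induced gene was higher: BaraC, a relative of BaraA2, stood at -1.60 (SD 1.07, 8 spots) and the immune-induced Diedel at -1.03 (SD 0.35, 7 spots) in the authors' deposited table, while the Bomanin BomS5 stood at 1.54 (SD 1.42, 8 spots). These 3 genes are outside the fixed lists and were chosen after their values were seen; with them the pooled count was 11 higher and 2 lower (two-sided Fisher's exact p = 0.0222). Listed markers of tissues other than trachea, pooled over 6 lists, lay on the same side, 8 higher and 0 lower. The two-sided Fisher's exact p, not adjusted, was 0.00774, and 0.0616 over genes with at least 8 spots. The authors chose the listed genes on these same arrays, so the counts are no independent evidence of direction. The infected larvae were also chosen by a reporter of the immune reaction, so higher immune genes may reflect that choice as well as the response.

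Signalling genes of the immune pathways were few. In the authors' deposited table the Toll list holds cact, the inhibitor of the pathway's transcription factors, at 1.46 (SD 0.66, 15 spots) and the protease gene grass at 1.32 (SD 0.36, 8 spots). The Imd list has a single entry in the authors' deposited table, akirin, a nuclear cofactor of Relish, at -1.32 (SD 0.69, 8 spots), and the JAK-STAT list has a single entry, the receptor gene dome, at -1.67 (SD 1.28, 6 spots). The melanisation list was split in the authors' deposited table, with ple and Ddc higher and yellow-f at -0.93 (SD 0.48, 8 spots) and MP1, a protease of the cascade, at -1.10 (SD 0.74, 6 spots).

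Genes of redox defence stood at 6 higher and 1 lower in the authors' deposited table, which did not pass Fisher's exact test (two-sided adjusted p = 0.405). They included, in the authors' deposited table, GstD3 at 2.15 (SD 1.06, 8 spots), cnc, the transcription factor of the antioxidant response, at 1.99 (SD 1.45, 8 spots), Irc, an immune-regulated catalase, at 1.61 (SD 0.61, 6 spots), and GstD2 at 1.42 (SD 0.97, 8 spots). All listed glutathione S-transferases together were 6 higher and 4 lower (adjusted p = 0.925, Fisher's exact test), with GstD9 at 1.95 (SD 1.18, 6 spots) and GstT3 at -1.77 (SD 0.63, 6 spots) in the authors' deposited table.

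Genes of the airway's own programme gave small counts. The tracheal development list has 2 entries in the authors' deposited table, the transcription factor genes salm at 2.09 (SD 1.58, 8 spots) and vvl at 1.97 (SD 0.55, 8 spots). The fixed list of cuticle protein genes was 3 higher and 1 lower (adjusted p = 0.902, Fisher's exact test), with Cpr64Ad at 1.93 (SD 1.63, 6 spots) and Lcp1 at -1.43 (SD 0.52, 8 spots) in the authors' deposited table. Outside that list, and chosen after their values were seen, Cpr67Fa2 stood at 1.51 (SD 0.91, 6 spots) and Cpr51A at -0.85 (SD 0.78, 8 spots) in the authors' deposited table. For the lumen and septate junction list, the authors' deposited table gives dpy at 1.05 (SD 0.45, 6 spots), Gasp at -0.70 (SD 0.56, 7 spots) and nrv2 at -1.71 (SD 0.64, 6 spots), and Fisher's exact test gave an adjusted p of 0.902. The ecdysone response list holds ImpL2, a secreted insulin-binding protein and the single entry of the insulin list, at 2.09 (SD 1.18, 17 spots) and EcR at 1.20 (SD 0.78, 6 spots) in the authors' deposited table. Glycolysis was represented in the authors' deposited table by Hex-A at 1.46 (SD 0.40, 6 spots) and Gpdh1 at 1.24 (SD 1.00, 22 spots), and heat shock proteins by Hsc70-3 at 1.42 (SD 0.49, 8 spots) and Hsp60A at 0.93 (SD 0.33, 6 spots).

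**Figure D1:**
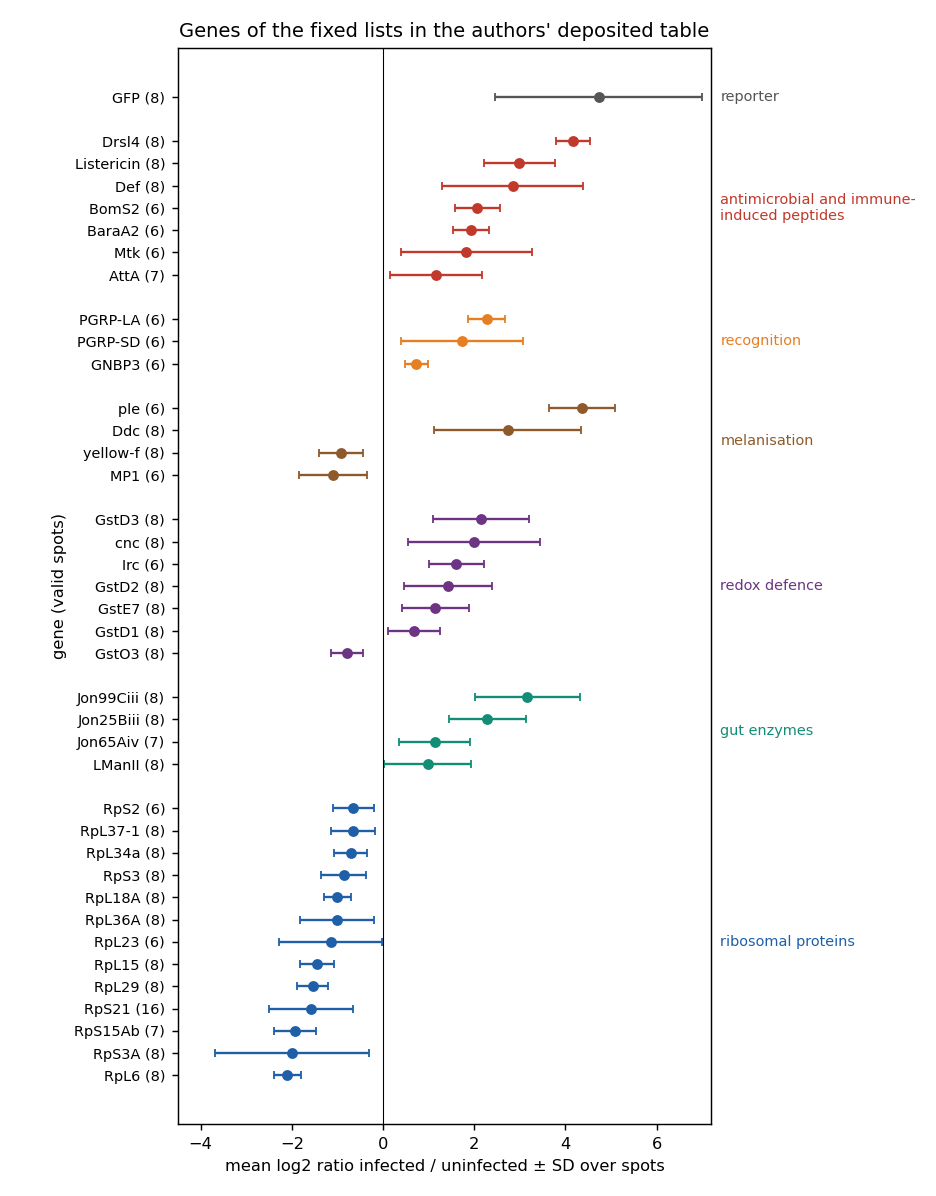
Mean log2 ratio of infected over uninfected trachea (x axis) for GFP and for the members of 7 fixed lists that are in the authors' deposited table, with the number of valid spots in brackets. Points are the authors' means and bars the SD over spots; the 10 immune peptide and recognition genes lie above 0 and the 13 ribosomal protein genes below 0, down to -2.10 for RpL6.

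The clearest group was that of the cytosolic ribosomal proteins. Of 92 genes with a ribosomal protein symbol, which formed the fixed list, 13 are in the authors' deposited table and all 13 are lower, with a median of -1.15 and a range from -0.65 to -2.10. This was the 1 list of the 13 tested that passed the threshold (two-sided Fisher's exact p = 7e-05, adjusted p = 0.000907). The test counts genes as independent, which members of the same complex need not be. The lowest of the list in the authors' deposited table were RpL6 at -2.10 (SD 0.30, 8 spots), RpS3A at -1.99 (SD 1.69, 8 spots), RpS15Ab at -1.94 (SD 0.46, 7 spots) and RpS21 at -1.58 (SD 0.93, 16 spots). The list missed sta (CG14792), the gene of ribosomal protein SA, which stood at -2.06 (SD 0.78, 15 spots) in the authors' deposited table and was found after its values were seen; with it the count was 0 higher and 14 lower. Ribosomal protein genes are short, and genes listed as lower were shorter in general: the median genomic span was 1411 bp over 331 lower genes and 3229 bp over 352 higher genes (permutation p = 2e-05, the smallest that 100000 resamples can give). Within the range of spans of the 13 ribosomal protein genes, 637 to 1983 bp, the other listed genes were 110 higher and 165 lower, or 60% lower, and against these the list had a two-sided Fisher's exact p of 0.00226. When the genes were restricted to those with a coefficient of variation under 0.5, 5 ribosomal protein genes were left, all lower. Fisher's exact test gave an adjusted p of 0.288. The unadjusted Fisher's exact p was 0.0604, so 5 genes could not pass there even with all lower. The coefficient of variation is divided by the mean, so the size of a change also decides which genes stay. The housekeeping gene betaTub56D, by contrast, stood at 0.69 (SD 0.51, 8 spots) in the authors' deposited table.

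Functional terms given in the authors' deposited table pointed to a related but wider group. Of 67 terms with at least 8 listed genes, 4 passed the threshold, and all 4 leaned to the lower side, on which listed genes were also shorter. Structural constituent of ribosome had 2 genes higher and 25 lower (adjusted p = 7.82e-05, Fisher's exact test), and protein biosynthesis 3 higher and 26 lower (adjusted p = 0.000117, Fisher's exact test). Both terms share genes with the ribosomal protein list, and neither is limited to it. The term ribosome itself had 1 higher and 9 lower and did not pass (adjusted p = 0.0867, Fisher's exact test). The small nucleolar ribonucleoprotein complex had 0 higher and 10 lower (adjusted p = 0.0145, Fisher's exact test), and the small nuclear ribonucleoprotein complex 0 higher and 9 lower (adjusted p = 0.0229, Fisher's exact test). Nuclear mRNA splicing had 3 higher and 10 lower and the mitochondrial large ribosomal subunit 1 higher and 7 lower, and neither passed (adjusted p = 0.204 and 0.199, Fisher's exact test). Defense response had 26 higher and 11 lower, which missed the threshold after adjustment (adjusted p = 0.180, Fisher's exact test).

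Other complexes went both ways. Respiratory chain subunits were 6 higher and 7 lower (adjusted p = 0.925, Fisher's exact test), and proteasome subunits 2 higher and 4 lower (adjusted p = 0.812, Fisher's exact test). Vacuolar ATPase subunits were 2 higher and 2 lower (adjusted p = 1, Fisher's exact test). Both listed cytoplasmic tRNA synthetase genes were lower, LeuRS at -1.57 (SD 0.50, 6 spots) and ValRS at -0.68 (SD 0.62, 6 spots) in the authors' deposited table. The lists of JNK signalling, thioester proteins, lysozymes, cytochrome P450 genes, iron handling, cell cycle, haemocyte markers and serpins had 0 entries there. These lists do not hold every gene of a family: the authors' deposited table has the cytochrome P450 genes Cyp12d1-d at 0.89 (SD 0.26, 8 spots) and Cyp313a4 at -1.57 (SD 1.42, 8 spots), found after their values were seen.

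Listed markers of tissues other than trachea lay on the higher side. Of 101 markers of haemocytes, fat body, muscle, gut, salivary gland and neurons, 8 are in the authors' deposited table, 8 higher and 0 lower (two-sided Fisher's exact p = 0.00774). This p pools 6 lists that were planned as separate tests, and it is not adjusted. Over genes with at least 8 spots 5 markers were left (Fisher's exact p = 0.0616). Over genes with a coefficient of variation under 0.5, 2 were left (Fisher's exact p = 0.238). All markers left were higher, and so few genes could not pass that way, so the larger p reflects their number. The gut enzymes were 4 higher and 0 lower (adjusted p = 0.405, Fisher's exact test), and 4 genes, all higher, could not pass. Next to Jon99Ciii, the authors' deposited table has Jon25Biii at 2.29 (SD 0.84, 8 spots), Jon65Aiv at 1.13 (SD 0.77, 7 spots) and LManII at 0.98 (SD 0.95, 8 spots). Each of the fat body, muscle, salivary gland and neuron lists has a single entry in the authors' deposited table: the lipid droplet gene Lsd-1 at 2.45 (SD 1.24, 6 spots), Act57B at 1.73 (SD 1.42, 8 spots), the glue gene ng1 at 1.16 (SD 0.79, 8 spots) and elav at 1.04 (SD 0.64, 6 spots).

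**Figure D2:**
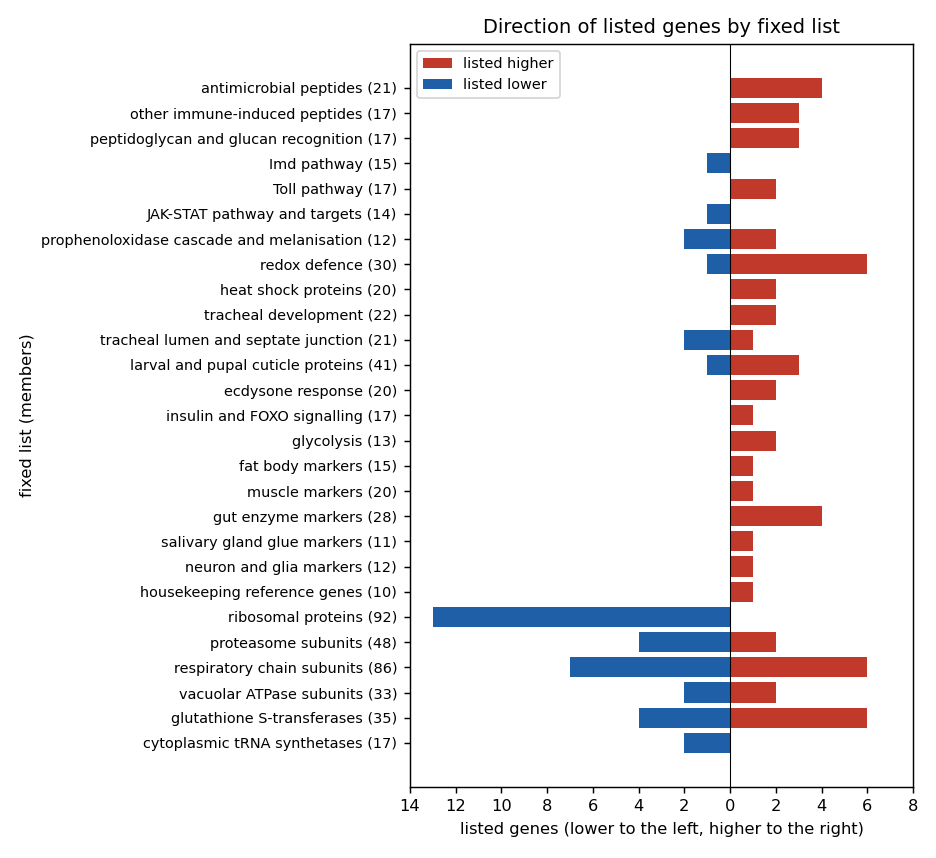
Number of genes of each fixed list (y axis, with its number of members) that the authors' deposited table gives as higher (right of 0) or lower (left of 0) in infected trachea. The ribosomal protein list has 0 higher and 13 lower, the antimicrobial peptide list 4 higher and 0 lower, and lists with 0 listed genes are not drawn.

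The same comparison was then made from the spot ratios of the arrays, with the 2 biological replicates as the unit of error. Of 16224 probes, 15 were higher and 4 lower in infected trachea (limma, Benjamini-Hochberg adjusted p under 0.05), and 1014 had an unadjusted p under 0.05. If no probe changed, a fraction of 0.05 of the 16224 would be expected under that unadjusted p, so many of the 1014 may be chance. Probes are given by spot number because the spots are not paired with gene names. GFP, by which the infected larvae were chosen, has a mean of 4.73 over 8 spots in the authors' deposited table. This is the highest mean there and also the mean of the largest called rise, so that rise is probably GFP. It would then reflect the choice of larvae as well as the response. The probe of spots 2685 and 2686 had the largest rise, with a mean of 4.73 ± 1.19 (SD, n = 2; limma adjusted p = 7.73e-05), followed by that of spots 13015 and 13016, at 4.27 ± 0.40 (SD, n = 2; limma adjusted p = 0.000348). The largest falls were those of spots 12037 and 12038, at -3.50 ± 0.31 (SD, n = 2; limma adjusted p = 0.00793), and of spots 12249 and 12250, at -3.32 ± 0.09 (SD, n = 2; limma adjusted p = 0.0148). The called rises ran from 2.99 to 4.73 and the called falls from -3.18 to -3.50, and 18 of the 19 probes had the same sign on all 4 arrays. The moderated standard errors of these 19 probes lay between 0.67 and 0.70, since limma's prior, shared by all probes, had 53.0 degrees of freedom against 1 between the replicates. Smaller changes were mostly beyond reach: in simulated data of the same spread, 25.5% of probes with a log2 change of 2 were recovered and 99% of those with a change of 4. With the 4 arrays as separate replicates limma called 35 probes, and 0 once the dye orientation was added to that fit as a term (1416 at an unadjusted p under 0.05). Without the array of replicate 2 that had the infected RNA in Cy5, 6 passed. The replicate as a random block gave 51, but the correlation within replicates estimated for that fit was -0.0282. The arrays of a swap pair were thus treated nearly as independent. After median centring of the arrays that correlation was 0.119, and the block fit called 5. The lean to the higher side also depended on the setting: against 15 higher and 4 lower, scaling the arrays to equal spread gave 28 and 14, SAM 42 and 32, and leaving out the replicate 2 array with infected RNA in Cy3 13 and 11.

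**Figure D3:**
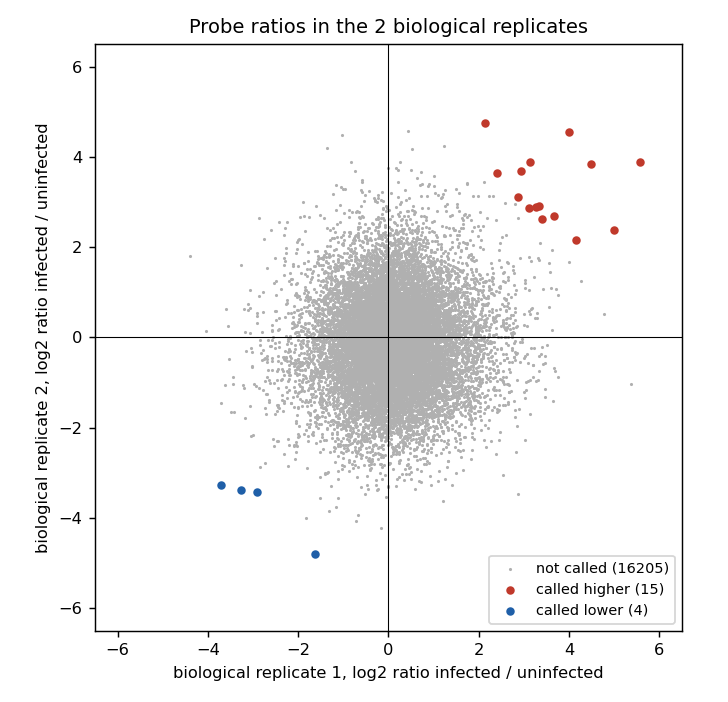
Log2 ratio of infected over uninfected trachea in biological replicate 1 (x axis) and replicate 2 (y axis), each the mean of a dye-swap pair, for 16224 probes. The 15 probes called higher (red) and 4 called lower (blue) lie far from the centre of a cloud with almost no slope (r = 0.0532).

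Repeatability was examined across probes, which are not independent replicates. The arrays of a dye-swap pair correlated at r = 0.380 in replicate 1 and r = 0.325 in replicate 2. The replicate means correlated at r = 0.0532 (Spearman's rho = 0.0373), and single arrays of different replicates at r between -0.0161 and 0.0724. Duplicate spots of a probe correlated at r between 0.496 and 0.614 on the 4 arrays, against 0.218 to 0.257 for adjacent spots that are not duplicates.

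Finally, the authors' deposited table was set beside the spot ratios without naming any spot. Of its 349 genes with 8 spots, 332 means and SDs in the authors' deposited table recurred in a pair of spots, within 0.006, against an average of 48.9 when the SDs were exchanged among genes. In 298 cases the match was to a single pair of spots. Of these, 133 had an unadjusted limma p under 0.05, and 6 passed the adjusted threshold. The 6 were all called higher. No called fall could be matched, since the called falls ran from -3.18 to -3.50 and the lowest mean in the authors' deposited table is -2.76. Both lists select large and even ratios from the same arrays, so their overlap is no check of either. With the probes of replicate 2 shuffled, an average of 1808 probes reached an absolute mean of 0.59, the smallest in the authors' deposited table, with a coefficient of variation under 1, against 2086 in the real data. At an absolute mean of at least 2 the shuffled average was 106, against 165, and at an absolute mean of at least 3 the shuffled average was 2.59, against 17. These criteria are not the authors' selection, which lists 695 genes, so the counts do not carry over to its entries. Limma called an average of 0.94 probes in the shuffled data (0 to 7), against 19. The shuffles also broke up any offset of an array region shared by both replicates.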

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

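The stricter subsets of the authors' deposited table, the centring of runs of spots, the combination of centring with a random block and all alternatives to the correlation of replicates were chosen after the data were seen; the others were planned. The count of called probes depended on the setting. Against 19 in the values as reported, limma called 35 with the arrays as separate replicates, 51 with the replicate as a random block, 33 after median centring, 42 after scaling to equal spread and 35 after centring each run of spots. A dye term added to the fit with separate arrays took its count from 35 to 0 (1416 at an unadjusted p under 0.05; SAM, run without that term, called 74), and centring with a random block left 5. The correlation within replicates estimated for the random block was -0.0282 without centring and 0.119 with it. With each array left out in turn the count ran from 6, without the replicate 2 array with infected RNA in Cy5, to 24. Robust moderation, and a minimum size of 1, gave 19. The rule of an absolute mean of at least 1 with the same sign on all 4 arrays, with no test, took 1467 probes, of which 192 were matched to the authors' deposited table, which was made from the same arrays. Those 1467 probes were 718 higher and 749 lower. The cause was not tested. Of the 19 called probes, all were kept under the random block, median centring and scaling, 18 with separate arrays and with centred runs, and 16 under SAM. With an array of replicate 1 left out 11 were kept in either case, with the Cy3 array of replicate 2 left out 15, with its Cy5 array left out 6, with centring and a random block 5, and with separate arrays and a dye term 0.

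In the authors' deposited table, the ribosomal protein genes stayed lower in each subset. They passed with at least 8 spots (10 genes, adjusted p = 0.00358, Fisher's exact test) and with absolute means of at least 1 (9 genes, adjusted p = 0.00819), and did not pass with a coefficient of variation under 0.5, where 5 genes were left (adjusted p = 0.288) and 0 lists passed. The antimicrobial peptide genes, all higher, were 4, 2 with at least 8 spots and 1 under the stricter variation. The 8 markers of other cell types became 5 (Fisher's exact p = 0.0616) with at least 8 spots, 7 (p = 0.0173) with absolute means of at least 1 and 2 (p = 0.238) under the stricter variation, with 0 lower. Fewer genes were tested in each subset. The 5 or 2 markers left, all higher, and the 5 ribosomal protein genes left under the stricter variation, all lower, could not pass at those counts. The correlation between replicates stayed between 0.0294 and 0.0888.

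Not run, because the probes carry no gene names: camera with preset or estimated correlation, fry, a gene value from the probe nearest the median, and the array-level alternatives for gene lists, antimicrobial peptides and markers. Without intensities no filter on dim probes was possible. With no missing values the rule on them moved nothing, and leaving out a whole replicate leaves no test.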

Other observations

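The groups and genes named first were chosen after their values were seen, and so were the tests further down, except those on gene span, which were set before their results were seen. Some components of the mitochondrial ribosome and of the splicing machinery lay on the lower side, and the functional terms gave a mixed result. The small nuclear ribonucleoprotein complex passed (adjusted p = 0.0229, Fisher's exact test), while nuclear mRNA splicing (adjusted p = 0.204) and the mitochondrial large ribosomal subunit (adjusted p = 0.199) did not. Of 11 mitochondrial ribosomal protein genes in the authors' deposited table, 10 are lower and 1 is higher (two-sided Fisher's exact p = 0.00471, not adjusted), among them mRpS18A at -1.96 (SD 0.38, 6 spots) and mRpL40 at -1.88 (SD 0.56, 8 spots), with mRpL27 at 1.31 (SD 0.94, 6 spots) as the exception. Sm and LSm proteins, the rings that bind spliceosomal and other small RNAs, were 0 higher and 6 lower (Fisher's exact p = 0.0125, not adjusted), with SmE at -1.45 (SD 0.22, 8 spots) and LSm3 at -1.80 (SD 0.78, 6 spots) in the authors' deposited table. The prefoldin subunits, which pass unfolded actin and tubulin to a chaperonin, were 0 higher and 3 lower (Fisher's exact p = 0.113, not adjusted), Pfdn5 at -2.12 (SD 0.38, 7 spots) being the lowest in the authors' deposited table. Tim13, a partner of the small Tim chaperones like Tim9a, stood at -1.73 (SD 0.20, 6 spots) in the authors' deposited table.

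On the higher side, Pu, which encodes GTP cyclohydrolase, the source of the pterin cofactor of tyrosine hydroxylase, stood at 1.46 (SD 0.93, 6 spots) in the authors' deposited table, next to ple and Ddc. The nimrod-type genes NimB4 at 2.05 (SD 0.60, 6 spots) and NimB2 at 1.65 (SD 0.65, 8 spots) in the authors' deposited table encode secreted relatives of phagocytosis receptors. Acyl-CoA binding proteins were 4 higher and 1 lower (Fisher's exact p = 0.375, not adjusted), from Acbp2 at 1.88 (SD 0.58, 8 spots) to Acbp1 at -1.64 (SD 0.87, 8 spots) in the authors' deposited table.

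The first pattern is that dye-swap pairs repeated each other while the biological replicates hardly did. Random spot noise is argued against: in the 4062 probes with the closest duplicate spots the swap pairs reached r = 0.600 and 0.601, and the replicates r = 0.0888. Offsets between regions of the array that hide an agreement of the replicates are argued against too. Once each run of spots was centred, r was 0.0294 and Spearman's rho 0.00531, against 0.0532 and 0.0373 before. Part of even that small agreement may thus rest on regions. The correlation of swap pairs was not computed after centring, so their agreement may hold such offsets too. Chance pairing of unrelated replicates gave 1808 of 2086 probes (86.7%) at the smallest listed size. It gave 106 of 165 (64.0%) at an absolute mean of at least 2 and 2.59 of 17 at one of at least 3. Chance pairing falls short of these counts, yet many probes that meet these criteria, up to and above a mean of 2, may rest on it. The criteria took 2086 probes, while the authors' deposited table lists 695 genes, so they are not the authors' selection. The share of its entries that rests on chance pairing therefore cannot be read from these counts. The shuffles moved probes across the whole array, so they also broke up any offset of a region shared by both replicates. Whether such offsets make up part of the excess was not tested. A true difference between the 2 infections, and a difference between 2 amplifications of small RNA samples, both stay open as causes of the low correlation, because each replicate was amplified from its own RNA.

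The second pattern is the lower level of the cytosolic ribosomal protein genes. Uncentred arrays do not account for it, since the median over all probe means was 0.00125 and the highest of the 13 genes stood at -0.65, nor do genes with few spots, since with at least 8 spots the list kept an adjusted p of 0.00358 (Fisher's exact test). Gene length as the whole cause is argued against by the other listed genes of the same range of spans (Fisher's exact p = 0.00226), but 60% of those were lower too, so part of the pattern may rest on length. Shorter spans on the lower side were general: the ratio of median spans, higher over lower, was 2.29 over all listed genes, 1.95 without ribosome, translation and ribonucleoprotein genes, and 2.18 with at least 8 spots. An effect of amplification on short or abundant transcripts, whose own lengths and intensities were not analysed here, and a response to the infection both stay open, and the latter was not tested apart from the former.

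The third pattern is that the 8 listed markers of other tissues are all higher. Attached tissue of other kinds could raise them. It was predicted to bring most markers into the authors' deposited table, and 7.92% of 101 were listed. That share cannot decide, because only genes selected by the authors are listed and a single attached tissue need not raise the other lists. Attached tissue is not excluded, because 0 of the 8 were lower. The major fat body and glue genes, such as Lsp2, Fbp1 and Sgs3, have no entry in the authors' deposited table, and the probes could not be searched for them by name. Attached tissue and a response of the airway cells themselves cannot be told apart here, since several of the markers may be expressed in trachea and none of the 8 was chosen independently of these arrays.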
